A study of Homo sapiens with 4 samples.

How the data were processed

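Nrf2 was immunoprecipitated from sonicated nuclei of SAS parental cells and SAS sphere cells, and each had an input without antibody. The labels' protocols describe 1 growth protocol, in which spheres formed over about 4 weeks in medium with 10 ng/mL basic fibroblast growth factor and 10 ng/mL epidermal growth factor. Libraries were amplified for 15 PCR cycles, and fragments of about 250 bp, adaptors included, were isolated from a gel, per the labels' protocols. Groups were taken from the labels, with 1 library in each of the 4 groups.

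The authors deposited 1 peak list per cell type. Each list gave the region, centre, length, peak shape score and p-value of every peak. Reads were aligned to GRCh38, per the submitters' processing notes. The aligner and the name of the peak caller are not given in the sources used here. Peaks were called on the Nrf2 library against the input of the same cells, without pooling, per the file headers. Those headers name a band width of 300, model fold limits of 10 and 30, a regional background over 10000 bp, scaling of the larger dataset to the smaller, and a p-value cutoff of 1e-05.

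The deposited p-values reached 0.05, so the cutoff named in the headers had not been applied to the listed peaks: 84.0% of parental and 98.5% of sphere peaks had a larger p. The authors' peak shape score was never below 1.645. In every peak where it could be tested, the deposited p-value equalled the upper tail of a standard normal distribution at the score within 5%. The score and the p-value therefore carry the same information. For 87 sphere peaks the p-value was listed as 0. No read counts or coverage were used here, so the depth behind each peak is unknown and the precision of a single score cannot be stated.

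Everything else was computed from these lists with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. Gene intervals came from a RefSeq table of the same build, which gave the start, end and type of each gene and neither strand nor exons. Distances to a transcription start were planned. They were replaced by distances to either end of a gene, because the start could not be told from the end. The planned search for the antioxidant response element in peaks, with its control windows, was not run because no genome sequence was used here.

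Overlap was counted as parental regions that shared at least 1 bp with a sphere region, on chromosomes 1 to 22, X and Y. It was set beside 1000 random placements of the parental regions on the same chromosomes. As a further background, each parental peak was moved at random by 20 to 200 kb to either side. For counts by gene, the parental peaks nearest the same protein-coding gene were moved together in 1000 random placements. Displacement was measured from each parental centre to the nearest sphere centre within 1 kb. Location was the share of peak centres within 1 kb of an end of a protein-coding gene, with 100 random placements of the parental list and 2 of the sphere list. The 2 lists were compared by Fisher's exact test.

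The 9 gene lists with their main tests, the share of peaks near the start of a gene and its test, the overlap of at least 1 bp beside random placements, and the rule for named genes were fixed before the data were examined. The displacement and its tests, counts by nearest gene, the share inside genes and its test, local random moves, lists matched on surrounding sphere peaks and the comparisons of windows were chosen after seeing the data. The lists were Nrf2 targets, stemness, epithelial-mesenchymal transition, keratinocyte differentiation, glycolysis, endoplasmic reticulum stress, proteasome, regions amplified in head and neck cancer, and markers of other cell types. Of 174 list entries 173 were found as protein-coding, 1 of them under a newer symbol, and 1 was left out. MYC stood in both the stemness and the amplified-region lists. A list was tested by Fisher's exact test (two-sided) of its genes with a peak centre within 5 kb of a gene end against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 18 tests of 9 lists in 2 cell types. Named genes were the nearest protein-coding gene of the 20 highest-scoring peaks per cell type, up to 4 genes per list by score, the genes with peaks in both cell types that had the highest parental scores, and 6 canonical Nrf2 targets. Chromosomal regions were described in 1 Mb windows and were chosen after their values had been seen, as was the p-value level of 1e-05 used for strong peaks.

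Alternatives were a stricter p-value of 0.005 or 1e-05, other overlap rules, distances of 1, 5 and 50 kb, the highest-scoring 10% of each list, all genes in place of protein-coding ones, and 10000 random lists matched on gene length or on the number of sphere peaks around the gene. The scripts were tested on simulated data. For the comparison of positions, 50 of 82 peaks were planted at a displacement of 300 bp towards the lower coordinate. Of all 82, planted or not, 42 had the nearest simulated centre within 100 bp of it, and the median was -284 bp. For the gene lists, 99.5% of 200 simulated lists of 37 genes with 25.0% of genes bound against 5.0% elsewhere were called, and 4.5% of unchanged lists were. These calls used unadjusted p-values. In the data 0.309% of genes had a peak in parental and 91.9% in sphere cells, so the simulation does not give the power of the list tests.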

Results

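Binding of Nrf2, the transcription factor that activates antioxidant and detoxification genes, was profiled by chromatin immunoprecipitation and sequencing in SAS cells, a human head and neck squamous carcinoma line. The 4 samples fell into 4 groups of 1 library each: parental cells and sphere cells, each with an Nrf2 immunoprecipitate and an input. Growth as spheres in defined medium is used to enrich for cells with stem-like properties. The 2 peak lists, 1 per cell type, gave the Nrf2 library against the input of the same cells. They carried no read numbers, so the depth of the libraries is unknown, and with 1 library per group no difference between the cell types had a replicate check. Tests below therefore compare 2 lists, or genes within a list, and not the 2 culture conditions. Peaks with p of 1e-05 or less, the cutoff named in the file headers, are called strong peaks. Coordinates are on GRCh38, and intervals on shares are exact 95% Clopper-Pearson intervals that cover counting error only and take peaks or genes as independent.

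The first comparison asked where the peaks of the Nrf2 library lay in parental cells. The 14 strong peaks of the parental list on chromosomes 1 to 22, X and Y lay at 6 genes only. Of these, 6 lay in NFE2L2, the gene of Nrf2 itself, 3 in BAG2, which encodes a co-chaperone of Hsp70, and 2 in S100A4, a calcium-binding protein linked to cell motility. The remaining strong peaks lay at the ends of MMP9, a secreted gelatinase, PGK1, an enzyme of glycolysis, and EEF1A1, a translation elongation factor. No gene of the well-known antioxidant set (NQO1, HMOX1, GCLM, TXNRD1, SRXN1 and SLC7A11) had a parental peak of any strength within 13 Mb. With only 82 parental peaks on these chromosomes, genes of other lists lay as far from one.

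The highest parental score, 19.2, belonged to the BAG2 peak at chromosome 6, 57183849 to 57184109. The other BAG2 peaks, at 57172631 to 57172879 and 57181963 to 57182210, scored 8.65 and 8.23. BAG2 itself spans 57172326 to 57189833. The 6 NFE2L2 peaks lay between 177230789 and 177234258 on chromosome 2, near the lower-coordinate end of a gene that spans 177230303 to 177264727, and scored 5.12 to 12.4. A weaker NFE2L2 peak, with a score of 2.24, lay near the other end of the gene at 177264431 to 177264678. In S100A4 (chromosome 1, 153543621 to 153545806) the 2 peaks, at 153543716 to 153543964 and 153544595 to 153544856, scored 6.98 and 6.17. The MMP9 peak (chromosome 20, 46008752 to 46009018) scored 13.9 and had its centre 13 bp outside the gene. The PGK1 peak (chromosome X, 78103947 to 78104195) scored 8.84, with its centre 176 bp outside the gene, and the EEF1A1 peak (chromosome 6, 73520992 to 73521241) scored 4.78, with its centre 86 bp outside. Exons and strand were not analysed here, so peaks were placed only relative to gene intervals. At these 6 genes, binding cannot be told apart here from DNA copies of transcripts or DNA of plasmids.

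Below these, the 20 highest-scoring parental peaks took in MAGEB10 (score 3.94, inside the gene) and NANOG, a pluripotency factor (score 3.74, centre 638 bp outside the gene). They also took in SKOR1 (3.15, at 5613 bp), LTBP1 (3.08, at 30639 bp), HMGN1 (3.02, at 164 bp) and NDUFS7 (2.71, inside the gene). Of the 20 peaks, 13 had their centre inside a protein-coding gene.

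In sphere cells, strong peaks were found at 5 of the same 6 genes. NFE2L2 had 4, with scores of 4.34 to 33.3, and the highest lay at 177232104 to 177232305. BAG2 had 3 strong peaks that scored 19.6 to 28.8, S100A4 had 2 that scored 6.55 and 8.83, and MMP9 had 2 that scored 9.98 and 19.8. PGK1 had 1, with a score of 7.93. EEF1A1 had none, and its best sphere peak within 5 kb of a gene end scored 2.36. Among the 20 genes with the highest parental scores of the 61 with peaks within 5 kb of an end in both cell types, 5 further genes had a strong sphere peak there: HMGN1 (score 9.77), MSX1 (6.90), MAGEB10 (5.65), RAE1 (4.45) and NDUFS7 (4.41). The best sphere scores at CASZ1, PLXNA1, NANOG, DHX9 and SKI were 3.49, 3.40, 3.21, 3.11 and 1.90. RAB23 and ZNF451 shared the peaks of BAG2, and S100A3 and S100A5 those of S100A4, as neighbouring genes. Scores rank peaks within a list, so their sizes are not set against each other between the lists.

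**Figure D1:**
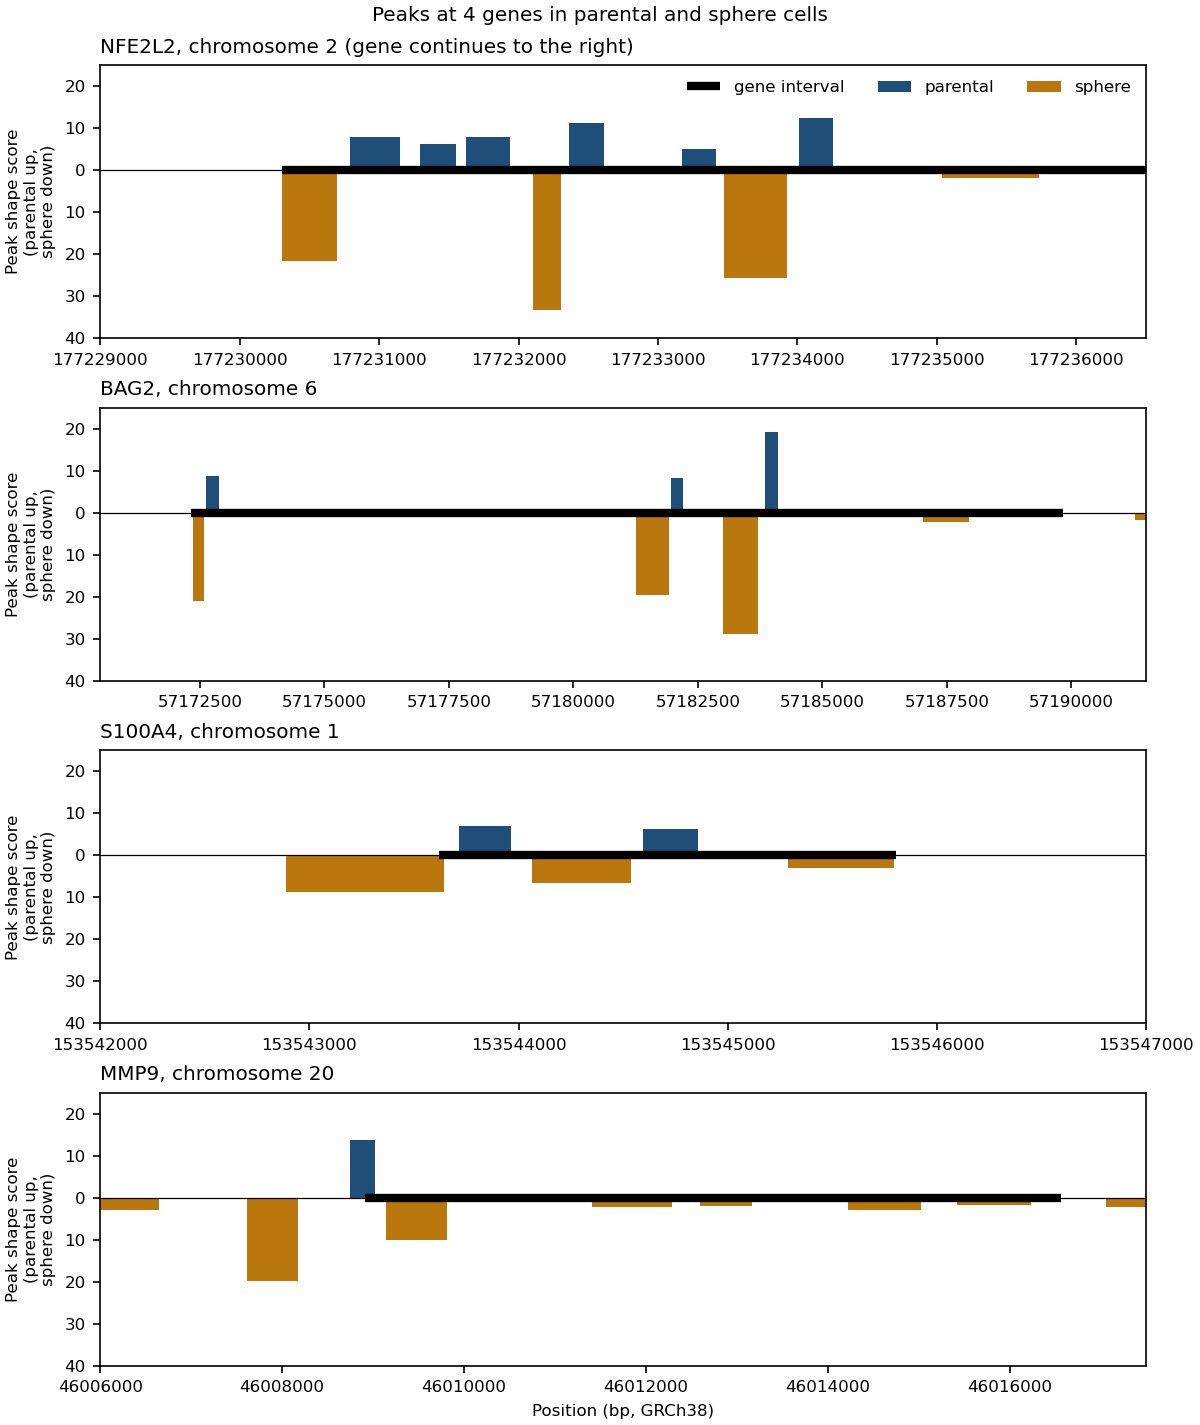
Nrf2 peaks at NFE2L2, BAG2, S100A4 and MMP9, with the position in bp on the x axis and the authors' peak shape score on the y axis, parental peaks drawn upwards and sphere peaks downwards. Each bar is 1 peak drawn to its length, the black line is the gene interval, and the strong peaks of the 2 lists lie beside each other rather than on top of each other.

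The second comparison asked how far the 2 cell types shared their peaks. Strong peaks were shared at the level of genes: 13 of the 14 strong parental peaks had the centre of a strong sphere peak within 1 kb, the exception being the EEF1A1 peak. As several peaks of a gene shared a sphere peak, genes were counted: 5 of 6 had such a peak (83.3%, interval 35.9 to 99.6), against at most 1 in 1000 random placements that moved the peaks of a gene together. Among all 82 parental peaks on these chromosomes, 66 had a sphere centre within 1 kb (80.5%), against a median of 32 and a maximum of 48 in 1000 random placements; counted by nearest gene it was 55 of 70 (78.6%, interval 67.1 to 87.5), against a maximum of 45. The regions themselves rarely met. Only 2 of the 82 parental regions shared at least 1 bp with a sphere region (2.44%, interval 0.297 to 8.53), while random placement of the parental regions gave a median of 18 and a range of 8 to 32. No placement gave as few as the 2 observed. This held for all listed sphere peaks: with the highest-scoring 10% of the sphere list the overlap was also 2, against a random median of 1 (range 0 to 7).

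Sphere centres lay mostly to one side of the parental ones. The values at the 3 BAG2 peaks were -345, -284 and -278 bp, where a negative value is a sphere centre at a lower coordinate. At the 2 S100A4 peaks they were -273 and -266 bp. The 6 strong NFE2L2 peaks went both ways, with -278, -279 and -293 bp at 3 of them and 396, 559 and 792 bp at the others, whose nearest sphere peaks were also the ones nearest to the parental peaks with -278 and -279 bp. Over the 66 parental peaks with a sphere centre within 1 kb the median was -285 bp, and 52 of the 66 sphere centres (78.8%) lay at the lower coordinate. Because neighbouring peaks can share a sphere centre, the test used the highest-scoring parental peak of each nearest gene: 44 of 55 lay at the lower coordinate (80.0%, interval 67.0 to 89.6; exact binomial test, two-sided, p = 8.7e-06). Within 100 bp of this median lay 45 peaks, against a maximum of 13 when each parental peak was moved at random by 20 to 200 kb. No sphere centre lay closer than 200 bp, where such moves gave at least 2. MMP9, at 312 bp, was also among the peaks with the sphere centre on the other side. Over the 45 peaks within 100 bp of the median, parental and sphere scores went together in rank (Spearman rho 0.548, permutation p = 7e-05). Among the 37 of them that were not strong in the parental list, rho was 0.275 (permutation p = 0.0984). The permutation takes peaks as independent, while the strong parental peaks among the 45 all lay in BAG2, NFE2L2 and S100A4. The rank correlation over the 45 therefore leans on few genes.

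**Figure D2:**
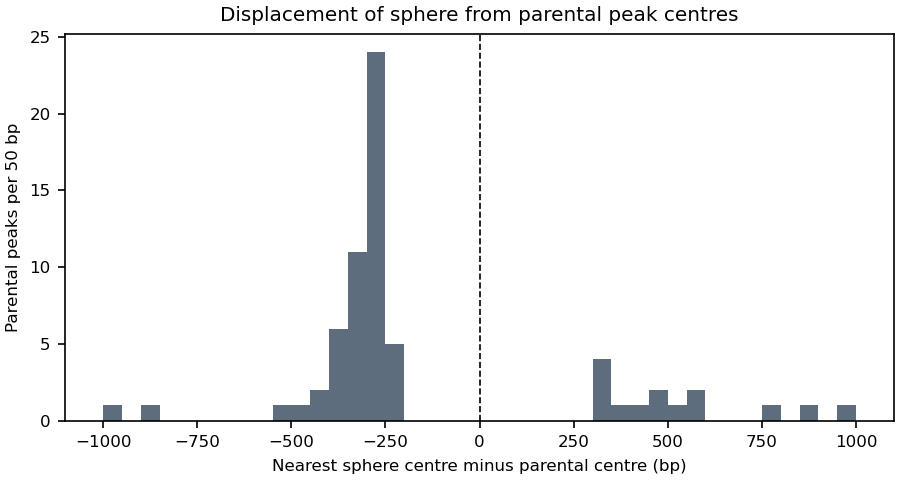
Distance in bp from each parental peak centre to the nearest sphere peak centre (x axis) against the number of parental peaks per 50 bp (y axis), for the 66 parental peaks with a sphere centre within 1 kb. Most peaks stand around the median of -285 bp, and none stands within 200 bp of the dashed line at 0.

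The lists differed in where their peaks lay relative to genes. Of the parental peaks, 39 of 82 had their centre within 1 kb of an end of a protein-coding gene (47.6%, interval 36.4 to 58.9), against 2.57% of randomly placed peaks. They included peaks at MMP9, PGK1, EEF1A1, NANOG and HMGN1. Of the sphere peaks, 20959 of 649420 did so (3.23%, interval 3.18 to 3.27), against 2.39% at random. The shares of the 2 lists differed by Fisher's exact test (two-sided, p = 7.1e-36). Inside a protein-coding gene lay 72.0% of parental and 48.5% of sphere peaks (Fisher's exact test, two-sided, p = 2.0e-05), with 41.8% and 42.5% at random. Both tests take peaks as independent, although some genes held several parental peaks, such as 7 in NFE2L2. Of the strong sphere peaks, 2.59% lay within 1 kb of a protein-coding gene end (interval 2.29 to 2.93) and 42.9% inside such a gene. These shares were near the 2.39% and 42.5% of the whole sphere list placed at random. Random placements also fell in gaps of the assembly, which lowers the random shares.

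The third comparison asked which groups of genes had Nrf2 peaks, using 9 lists and peaks within 5 kb of a gene end. In parental cells, 62 of 20050 protein-coding genes (0.309%) had such a peak. Of the 15 genes of epithelial-mesenchymal transition, MMP9 and S100A4 had one (13.3% against 0.299% of other genes; Fisher's exact test, two-sided, p = 0.000963, adjusted over 18 tests p = 0.0173). This was the only list past the threshold in parental cells, and it rested on 2 genes: with length-matched random lists the adjusted p was 0.0648, and with peaks within 50 kb it was 0.13. Of the 37 Nrf2 target genes only NFE2L2 had a peak (2.7%, exact test, adjusted p = 0.488). NANOG was the only one of 20 stemness genes (5.0%, exact test, adjusted p = 0.361) and PGK1 the only one of 15 glycolysis genes (6.67%, adjusted p = 0.361). None of the 20 keratinocyte genes, 15 endoplasmic reticulum stress genes, 24 proteasome genes, 12 genes of regions often amplified in head and neck cancer or 15 markers of other cell types had one (exact tests, adjusted p = 1.0 for each).

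The nearest parental peak to the 6 antioxidant genes lay 17.8 Mb from NQO1, 14.8 Mb from HMOX1, 13.7 Mb from GCLM, 96.4 Mb from TXNRD1, 45.4 Mb from SRXN1 and 96.9 Mb from SLC7A11. Parental peaks were sparse, with 1 on chromosome 12, which holds TXNRD1, and 1 on chromosome 22, which holds HMOX1. Such distances are therefore not particular to antioxidant genes. In sphere cells all 6 genes held peak centres, and none of these was a strong peak. NQO1 (chromosome 16, 69709401 to 69726560) held 6, and the highest scored 3.14. SLC7A11, the cystine transporter subunit, held 6 with a highest score of 3.39. TXNRD1 held 26 (highest 2.81), GCLM 12 (2.95), HMOX1 6 (2.64) and SRXN1 3 (2.54). Such counts depend on gene length and on how dense sphere peaks were around the gene. The 1 Mb windows held 423 sphere peaks for NQO1, 133 for SLC7A11, 167 for TXNRD1, 384 for GCLM, 291 for HMOX1 and 251 for SRXN1. Whether these genes held more peaks than their surroundings was not tested.

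Sphere peaks lay near nearly all genes. A sphere peak lay within 5 kb of an end of 18424 of the 20050 protein-coding genes (91.9%), and of 61 of the 62 genes with a parental peak. The Nrf2 target list, with 35 of 37 genes (94.6%), stood at about the level of the other genes (91.9%, exact test, adjusted p = 1.0). The remaining lists ranged from 86.7% for markers of other cell types, which a carcinoma line is not known to use, to 100% for the epithelial-mesenchymal, glycolysis and proteasome lists. No list passed the threshold in sphere cells, and shares this close to 100% leave little room for one to do so.

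With strong peaks only, 517 genes remained in sphere cells. Of the stemness list MYC, LGR5 and EPCAM were among them (3 of 20, 15.0% against 2.57% of other genes, adjusted p = 0.0824 by Fisher's exact test). LGR5, a Wnt pathway receptor of stem cells, held 22 strong peaks along its length, in a 1 Mb window with 550 sphere peaks, where the median window held 204. Of the amplified-region genes MYC and PPFIA1 were among them (2 of 12, 16.7%, exact test, adjusted p = 0.133), and the highest peak in PPFIA1 scored 15.7. The windows of MYC and PPFIA1 held 558 and 500 sphere peaks. NFE2L2 was the only one of the 37 Nrf2 target genes, and TALDO1, PIR and TXN followed with best scores of 3.95, 3.61 and 3.48. Of the epithelial-mesenchymal list MMP9 and S100A4 were again the members with strong peaks, and SNAI1 and SNAI2 followed with scores of 3.79 and 3.43.

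Among genes of the other lists, the best sphere scores near a gene end were 7.93 for PGK1, 3.73 for PGAM1 and 3.46 for HK2 in glycolysis, and 3.77 for CALR and 3.44 for PDIA6 in endoplasmic reticulum stress. They were 4.06 for PSMD12 and 3.80 for PSMA7 in the proteasome, 3.61 for ITGA6 and 2.87 for SPRR3 among keratinocyte genes, and 3.53 for PECAM1 and 3.15 for GCG among markers of other cell types.

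When only the highest-scoring 10% of the sphere list was used, 2 lists passed the threshold. Of the amplified-region genes, 9 of 12 had such a peak (75% against 29.0% of other genes, exact test, adjusted p = 0.0232), and of the keratinocyte genes 1 of 20 (5.0%, adjusted p = 0.0485). The exact test takes genes as independent, but CCND1, ANO1, FADD, PPFIA1 and CTTN are neighbours on chromosome 11, in windows with 500 to 532 sphere peaks. Against random lists matched on the sphere peaks of the window, a setting chosen after seeing the data, neither list passed (75% against 53.8% and 5.0% against 19.1%, adjusted permutation p = 0.411 for both). The Nrf2 target list stood at 29.7%, with 11 of 37 genes.

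The fourth comparison asked how many peaks each list held and how they were spread over the chromosomes. The parental list held 94 peaks, of which 12 were mitochondrial, and the sphere list held 649427, of which 7 were. At the strong level 15 and 9803 peaks remained. The median score was 1.99 in the parental and 2.11 in the sphere list, so most peaks of both lists were weak. Parental regions had a median length of 256 bp and covered 0.0253 Mb in all, while sphere regions had a median of 764 bp and covered 484.2 Mb.

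Sphere peaks filled long stretches of some chromosomes and spared others. On chromosome 8, the stretch from 100 to 140 Mb, which holds MYC, had 519.8 peaks per 1 Mb window and 1496 strong peaks, while the stretch from 0 to 45 Mb had 37.6 per window and 7 strong peaks. On chromosome 3, the first 5 Mb held 6 peaks in all, and the windows from 100 to 190 Mb averaged 381.4. Chromosome 4 averaged 103.0 per window over its length. Over 2974 windows the median was 204 peaks (quartiles 105 and 322).

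Strong sphere peaks were crowded into few places. The 20 windows with the most strong peaks held 4518 of the 9483 strong peaks in windows (47.6%), and 2140 windows held none. Chromosome Y, with 314 strong peaks, was not part of the windows. On chromosome 12, the 5 to 6 Mb window with NTF3, VWF and KCNA5 held 591 peaks, 576 of them strong (97.5%), and peaks covered 44.8% of it. Windows from 15 to 24 Mb of that chromosome averaged 17.8 peaks. The 167 to 169 Mb region of chromosome 5, with TENM2 and WWC1, held 939 peaks, of which 479 were strong, while the 161 to 166 Mb windows averaged 128.4 and held no strong peak.

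**Figure D3:**
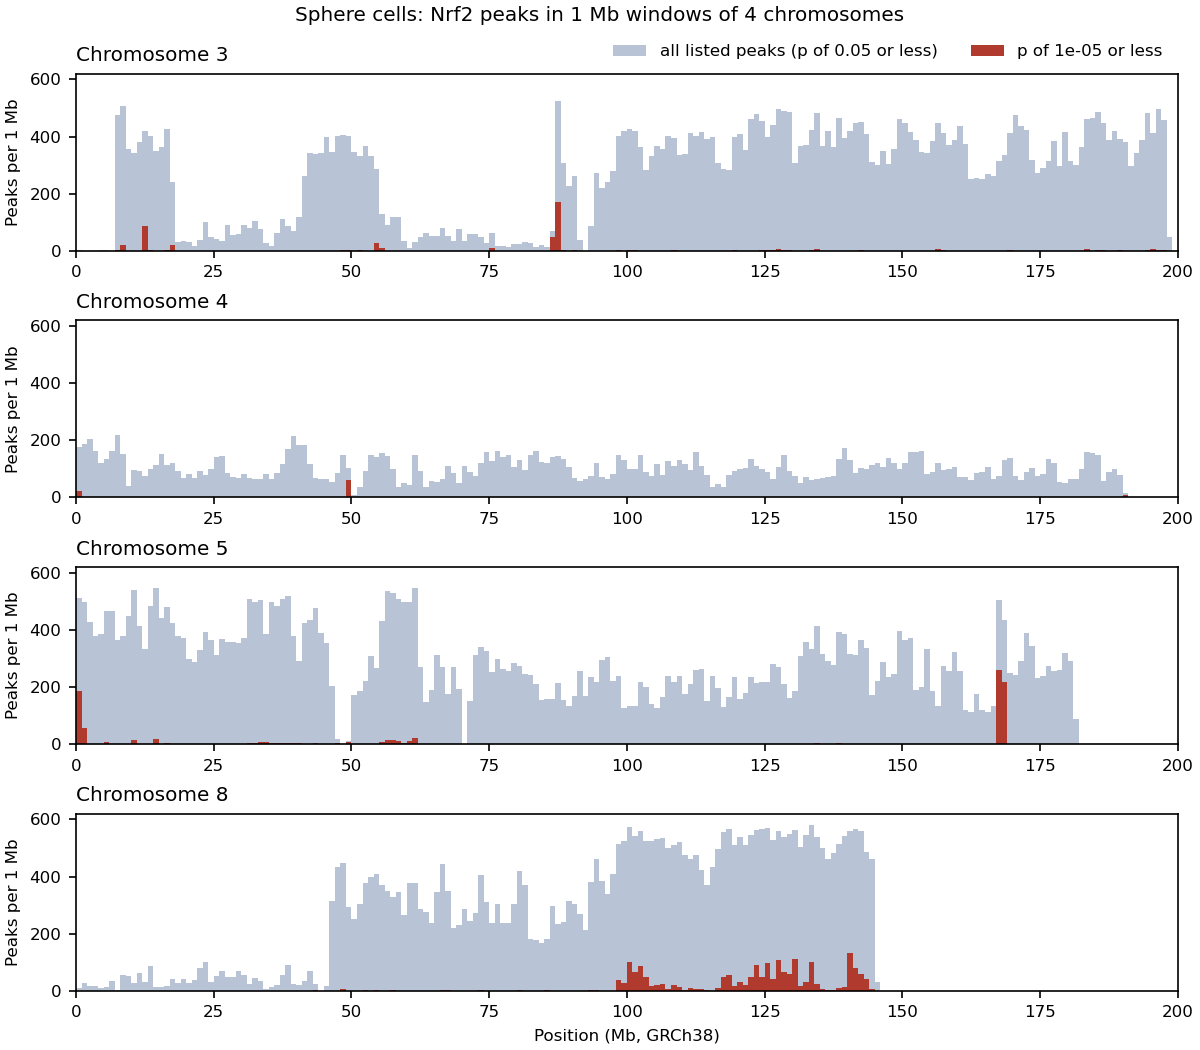
Number of sphere peaks in 1 Mb windows (y axis) along chromosomes 3, 4, 5 and 8 (x axis, in Mb), with all listed peaks in grey and strong peaks in red in front of them. The counts change in steps along chromosomes 3 and 8, from 37.6 per window in the first 45 Mb of chromosome 8 to 519.8 between 100 and 140 Mb, and the 167 to 169 Mb region of chromosome 5 holds 479 strong peaks.

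The highest-scoring sphere peaks lay far from genes. None of the 20 highest lay inside a protein-coding gene, and the nearest gene was 96533 to 3720773 bp away, with a median of 297864 bp. The highest of all, with a score of 180.7, lay on chromosome 16 at 46390137 to 46390968, and SHCBP1 was its nearest gene at 187962 bp. Of the 20 peaks 9 were on chromosome 16, where SHCBP1 was the nearest gene of 5 and LOC124903767 of 4. The next highest lay on chromosome 3 at 93470023 to 93470531 (score 176.6), 402750 bp from PROS1. For the others the nearest gene, at 96533 to 3720773 bp, was CWH43 on chromosome 4, EMB on chromosome 5, LOC102723475 on chromosome 21, LINC02798 on chromosome 1 or USP9Y on chromosome Y. Repeated sequence at these places was not analysed here, so whether these peaks reflect Nrf2 binding far from genes was not tested.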

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

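Mitochondrial peaks belonged to no comparison of the report and stand out as signal outside the nuclear chromosomes. The parental list held 12 such peaks, with scores of 1.73 to 4.63, and the sphere list held 7, with scores of 2.53 to 60.5. The parental peaks lay between 827 and 9191 bp of the mitochondrial genome. Of the sphere peaks, 1 at 16105 to 16569 bp crossed the origin and scored highest.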

How the results depend on the processing

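The level of 1e-05, the moved sphere regions, local random moves, the share inside genes and lists matched on surrounding sphere peaks, with all peaks and with the highest-scoring 10%, were chosen after seeing the data, as were counts by nearest gene and the displacement with its test; the other settings given here were planned. No paired analysis was possible because each group had 1 library, and no library could be left out. Peak numbers fell to 33 parental and 140922 sphere peaks at p of 0.005, and to 15 and 9803 at 1e-05. The overlap of 2 peaks became 0 with 50% reciprocal overlap, 66 with centres within 1 kb, 50 with sphere regions moved by the median displacement (which restates that displacement, as it came from the same peaks), and 13 of 14 among strong peaks within 1 kb. Counted by nearest gene it was 55 of 70 for all peaks and 5 of 6 for strong peaks within 1 kb, so it depended on the rule. The parental share near gene ends rose to 72.0% within 5 kb and was also 72.0% inside genes. The sphere share was 12.8% within 5 kb, 7.41% with ends of all genes, 3.83% in the highest-scoring 10%, 2.59% at 1e-05 and 48.5% inside genes. In parental cells the number of gene lists past the threshold went from 1 to 0 within 50 kb, to 3 in the highest-scoring 10% and to 0 with length-matched lists. In the highest-scoring 10% the Nrf2 target list, still at 2.7% through NFE2L2 alone, had an adjusted p of 0.0485. In sphere cells the number went from 0 to 2 in the highest-scoring 10%, keratinocyte genes (5.0%) and amplified-region genes (75%), both of which changed direction against the other genes. With the highest-scoring 10% and lists matched on surrounding sphere peaks it was 0 again. With all peaks 91.9% of genes had one, which left little room for lists to differ; the cause of the other changes was not tested. Of 108 alternatives for single lists, 87 kept direction and side of the threshold, 17 changed direction, 2 newly passed the threshold in the same direction (Nrf2 targets and glycolysis in parental cells, highest-scoring 10%) and 2 no longer passed it. Of the 17, the 2 lists named for the highest-scoring 10% in sphere cells also newly passed it. The other changes of direction, none past the threshold, were in parental cells stemness genes to 0% in the highest-scoring 10% and at 1e-05. In sphere cells they were stemness and keratinocyte genes to 55.0% each and amplified-region genes to 83.3% within 1 kb, and amplified-region genes and markers of other cell types to 100% each within 50 kb. They were also keratinocyte, endoplasmic reticulum stress and proteasome genes to 0% each and amplified-region genes to 16.7% at 1e-05, and endoplasmic reticulum stress genes at 93.3% against lists matched on surrounding sphere peaks. With such lists in the highest-scoring 10% they were keratinocyte genes (5.0%), proteasome genes (33.3%) and amplified-region genes (75%). Not run were the response element search, thresholds on fold enrichment, and the authors' own annotation columns. Unknown depth limits every comparison of peak numbers.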

Other observations

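Some weak parental peaks lay at genes that no comparison above names. The genes given here were chosen after their values were seen, and no test speaks for them as a group. PROM1, which encodes the stem cell marker CD133, held 3 parental peaks on chromosome 4, with scores of 1.66, 1.74 and 1.99, none of them within 5 kb of a gene end. HES5 and HEY1, effectors of the Notch pathway, had peaks with scores of 1.99 and 1.90, and FOXD1 and MAFA had peaks with scores of 1.83 and 1.78. SOD2, the mitochondrial superoxide dismutase, held a peak with a score of 2.20.

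All tests in the paragraphs that follow were chosen after the patterns had been seen, and for 2 of them, both on gene density, the outcomes that would decide were written down before their own value was computed.

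Sphere peaks filled long blocks of chromosomes, such as the part of chromosome 8 that holds MYC. Gene density as the whole cause is argued against, since neighbouring windows still went together after the gene count had been removed (Spearman rho 0.869 pooled over chromosomes, bootstrap interval 0.814 to 0.892, and a mean of 0.597 within chromosomes, interval 0.528 to 0.667). A part for gene density stays open: the rho between peak and gene counts was 0.371 over all windows (interval 0.279 to 0.472) and the rank correlation within chromosomes was 0.551, on either side of the 0.5 written in advance. Blocks of DNA copy number or of coverage, and broad Nrf2 binding that differs by region in sphere cells, cannot be told apart here. The rho of 0.863 between neighbouring windows, a mean of 0.721 within chromosomes, restates the pattern and would follow from both, and coverage of the inputs was not analysed here.

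Strong parental peaks lay at 6 genes, and 0 of the 36 other genes of the Nrf2 target list had one. At PGK1 the strong regions of both lists lay wholly outside every gene, the outcome set against DNA copies of transcripts in the samples. The sphere region lay 516 bp outside, more than the displacement of -285 bp between the lists. The parental region lay only 53 bp outside, less than that displacement, and the displacement of this pair was -402 bp. Positions therefore cannot exclude such copies at PGK1. Elsewhere such copies cannot be told apart from binding either. At NFE2L2, BAG2 and S100A4 all 11 parental regions lay inside the gene, and no exons were at hand. A strong sphere region at S100A4, 153542890 to 153543645, lay mostly outside the gene, which starts at 153543621. At MMP9 and EEF1A1 both parental regions, 2 of 2, reached into the gene, with 58.4% and 83.6% of their length outside it. A strong sphere region lay 732 bp outside MMP9, and another lay inside it. Promoters of PGK1 and EEF1A1 are common parts of expression plasmids, and DNA of plasmids that carry promoters or transcript copies could give peaks at genes only, as seen for 14 of 14, but so could binding at these genes. Nrf2 bound near its known targets stays open for NFE2L2, since the test on the list's other genes says nothing about that gene.

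Sphere centres were displaced from parental centres by a median of -285 bp, with like values at the BAG2 and S100A4 peaks. Different binding positions in the 2 cell types would fall to both sides alike, and 80.0% to the lower side with 1 peak per gene (interval 67.0 to 89.6) argues against them as the whole cause, while leaving them open for the peaks on the other side, such as MMP9. An offset in where the sphere centres were placed may account for it and stays open. The displacement of -286 bp from odd-numbered autosomes was met within 100 bp by 23 of 47 peaks on the other chromosomes. Random local moves gave at most 9. This restates the displacement already seen over all peaks and would follow from any cause of it, so it cannot speak for an offset in particular. The 23 also count peaks of the same gene separately. Which step of the processing would give such an offset was not tested.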
